A study of Saccharomyces cerevisiae with 16 samples.

How the data were processed

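The series holds 16 RNA sequencing libraries labelled as a Δphm4 strain, 1 per time point: 0 min in high phosphate and every 15 min from 15 to 225 min without phosphate. Per the labels RNA was extracted with a 96-well column kit and the cDNA sequenced on an Illumina HiSeq instrument, and reads were aligned with Bowtie (version not stated) to build R64. The counting program, the annotation and the treatment of reads with several matches are not stated. The deposited table gives each gene's log2 value, which from the values themselves is the log2 of reads per 1000000 (CPM): raised back, each library sums to 1000000. The authors' description speaks of a normalization to the first time point, which the deposited values do not show, so ratios to 0 min were formed here by subtraction of log2 values. Low values of a library are multiples of a single step. This step was set by taking the lowest value as a floor of 20 reads, an assumption, and depth was recovered from it. Recovered reads of VTC1, another name of PHM4, were even in all 16 libraries. Those of HIS3, URA3 and PHM7 were even as well wherever these genes were listed. The true step is therefore probably larger by a factor of 2, and the true depths and read numbers are smaller by the same factor. Within a tolerance of 0.01 reads, 96.7% to 98.4% of the low values of the 14 deeper libraries and 90.3% to 90.4% of those of the 2 shallow libraries were whole reads. This check cannot tell the step used from the larger one. At 0 min 287 genes lay between steps, 103 of them among the 138 listed ribosomal protein genes, which have near-identical copies. Genes under the floor have no value, and no pseudocount was used.

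The table has 6701 entries. Of these, 51 have no name and no value, and 1 name that stands on 2 of them was left out, leaving 6648 genes. In all 5713 genes were listed in at least 1 library and 935 in none; 5482 of the listed names matched build R64, 905 were listed in all 16 libraries and 4495 in the 14 deeper ones. No mitochondrially encoded gene has a value. The floor was 244 CPM in the library labelled 195 min and 222 in that labelled 210 min, so these 2 libraries hold values for abundant genes only. Depths recovered are those of the listed genes, 1206852 to 6875746 reads in the deeper libraries. Poisson intervals were taken for VTC1.

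Tests, gene lists, thresholds and the rule for named genes were fixed before the data were examined. The slope of the log2 value on time over the 15 starvation libraries was tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), for 5282 genes with at least 8 values, a minimum chosen on seeing the missing values. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a fitted change of at least 1 (log2) from 15 to 225 min. A natural spline of 3 degrees of freedom was tested with limma's moderated F. Gene lists were tested on the slope with camera at a preset correlation of 0.01, adjusted over 29 lists. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance in one direction, need complete values and were run on the 4500 genes listed in the 13 deeper starvation libraries. Both were fitted over those 13 libraries alone. They differ from the preset camera in libraries and genes as well as in the correlation. Slope, camera, fry and permutation tests were two-sided. Lists enriched among spline genes were tested with a hypergeometric test, one-sided for enrichment, against the genes tested.

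Means and SDs of the ratio to 0 min over 15 to 60 min and over 180 to 225 min have no test, since 0 min is a single library; list medians were set against 10000 random lists matched on expression. Onset used a 3-point running mean, with end points keeping their own value. The rule named VTC1 and the marker genes, the 12 largest rises and falls among called genes with all 15 values (20 rose and 3 fell), the PHO regulon, up to 4 called members of each other list, the 8 highest and 8 lowest genes of the first hour, and 6 fitted peaks and 6 troughs, of which 4 peaks existed.

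Lists covered the PHO regulon, phosphate signalling and constitutive transport, polyphosphate metabolism, ribosomal proteins, ribosome biogenesis, general stress, trehalose and glycogen, Hsf1 chaperones, histones, G1/S, G2/M and M/G1 genes, oxidative phosphorylation, the TCA cycle, glycolysis, hexose transport and glucose-repressed genes, amino acid, sulphur, purine, ergosterol and phospholipid synthesis, the iron and zinc regulons, the proteasome, autophagy, mitochondrial ribosomal proteins, translation factors, pheromone response, other cell types, mitochondrially encoded genes and strain checks.

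Alternatives planned were other models of time, whitening of the lag-1 autocorrelation (0.36 around the line, 0.20 around the spline), leaving out each library, adding the 0 min library, centring, quantile normalization, genes listed in all 15 libraries, other variance models and thresholds, and other onset rules. Alternatives added after seeing the data were leaving out both shallow libraries, a minimum of 3 values, weights from read numbers, a spline of 5 degrees of freedom, fits on the genes complete in the deeper libraries, and the floor for genes not listed at 0 min. The plan kept count-based tools for a file of counts and pseudocounts for linear values, so neither was run on the recovered reads. On data simulated with independent scatter of the size left around the spline, 73% of genes with a true change of 1.5 passed the slope test. Of genes with a change of 2, 89.8% passed, as did 11 of 5073 flat genes. The simulation held no autocorrelation and no shift of the shallow libraries, so these shares do not describe the real libraries. Values were prepared with Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1) and plots drawn with matplotlib 3.10.9.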

Results

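RNA of a Saccharomyces cerevisiae strain labelled as lacking PHM4 was sequenced in 16 libraries from a time course of phosphate starvation. PHM4 is another name of VTC1 (YER072W, chromosome V, 302806 to 303195 in build R64), a subunit of the vacuolar complex that makes polyphosphate, the cell's phosphate store. The strain derives from BY4741 and carries a YFP reporter driven by the promoter of PHO84, the gene of the high-affinity phosphate transporter. A single library (0 min) came from high phosphate medium, and 15 libraries came from cells moved to medium without phosphate, 1 every 15 min from 15 to 225 min. No time point had a replicate, and a strain with intact PHM4 was not analysed here, so no value measures the effect of the deletion. The depth recovered from the values was 6875746 reads in the 0 min library and 2708184, 1206852, 3748602, 2086263, 2717246, 4560971, 3536464, 2518427, 4249926, 3794158, 2002157 and 1533058 reads in those of 15 to 180 min, in order of time. The library of 225 min held 3097324 reads. The libraries labelled 195 and 210 min held only 81968 and 90017 reads and listed 1122 and 1188 genes, against 4694 to 5475 genes in the 14 deeper libraries.

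The gene labelled as deleted and the auxotrophic markers of BY4741 served as checks of the strain. LEU2 and MET17, biosynthetic genes of leucine and methionine that BY4741 lacks, were listed in no library, HIS3 was listed at 0 min alone and URA3 at 0, 90 and 180 min. VTC1 was listed in every library. Its log2 reads per 1000000 (CPM) lay between 6.67 and 7.51 in the 14 deeper libraries. In the library labelled 195 min it was 10.80, or 1781 CPM from 146 reads (95% Poisson interval 1504 to 2095), and in that labelled 210 min 10.90, or 1911 CPM from 172 reads (1636 to 2219). Against the mean of VTC2, VTC3 and VTC4, which encode the other core subunits of the complex, VTC1 lay 0.55 lower at 0 min and 2.01 to 3.40 lower (log2) in the deeper starvation libraries, but 0.62 and 0.86 higher at the labels 195 and 210 min. Intervals cover counting error alone and rest on the step used. With the larger step the VTC1 reads would be fewer by a factor of 2 and the intervals wider.

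**Figure D1:**
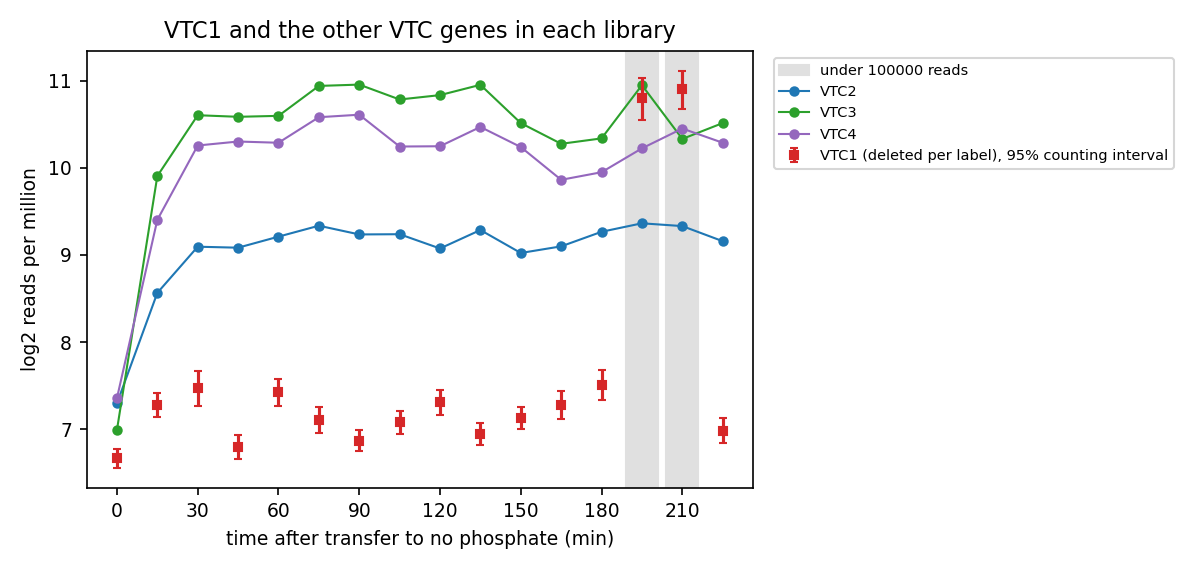
Log2 CPM of VTC1 (red squares) and of VTC2, VTC3 and VTC4 (lines) against time in minutes in each of the 16 libraries. Bars are 95% Poisson intervals of the recovered reads, too narrow if the true step is larger. Grey bands mark the libraries under 100000 reads. VTC1 lies at 6.67 to 7.51 in the deeper libraries and at 10.80 and 10.90 in the shaded ones.

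The first hour of starvation was compared with the 0 min library to ask which genes differed soon after transfer. All 16 PHO regulon genes with a value, the targets of the phosphate-responsive transcription factor Pho4, were at least 2-fold higher, with a median log2 ratio of 3.47 (range 1.05 to 4.45). PHO84 (chromosome XIII, 24037 to 25800) was 18.3-fold higher, a log2 ratio of 4.19 ± 0.31 (SD over 4 successive libraries, as for all values of this window). SPL2, which encodes a regulator of low-affinity phosphate uptake, was 16.3-fold higher (4.02 ± 0.36), and PHM8, which encodes a phosphatase of nucleotides, was 19.3-fold higher (4.27 ± 0.95). The acid phosphatase genes PHO11 and PHO12 were at 4.45 ± 1.13 and 4.07 ± 1.06. These near-identical copies may share reads, which was not examined, so their separate values are uncertain. The intact polyphosphate genes VTC3, VTC4 and VTC2 were 10.8, 6.52 and 3.23 times their 0 min level. The median of the PHO regulon exceeded that of every one of 10000 random lists of the same size matched on expression, whose central 95% ran from -0.32 to 0.69.

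Genes of the general stress response, induced under many adverse conditions, were higher too, 40 of 40 at least 2-fold, with a median of 2.78. Among them HSP42, a small heat shock protein, was 15.8-fold higher (3.98 ± 0.83). Outside the fixed lists RTC3 and RGI1, known as stress-inducible, were at 4.01 ± 0.80 and 3.85 ± 0.99. Trehalose and glycogen genes had a median of 2.08 (14 of 15 higher), vacuolar hydrolase and autophagy genes 1.53 (12 of 15) and sulphur and methionine genes 1.20 (12 of 20). Growth genes were lower: 51 of 54 ribosome biogenesis genes were at least 2-fold down, with a median of -1.77, as were 101 of 136 cytosolic ribosomal protein genes, with a median of -1.21. The 8 genes furthest below 0 min included the rRNA processing factors NSR1 (-2.89 ± 1.63), PWP2 (-2.64 ± 1.13), ENP2 (-2.54 ± 1.17), DBP3 (-2.46 ± 1.51) and HCA4 (-2.42 ± 1.07). The others were the RNA helicase gene DBP2 (-2.79 ± 1.42), the adenine deaminase gene AAH1 (-2.73 ± 1.57) and YLR413W (-2.70 ± 0.57). Of the markers of MATalpha, diploid or sporulating cells, 5 had a value, 4 were at least 2-fold higher and their median was 1.33. In all, 738 of 4615 genes were at least 2-fold higher and 392 lower in the mean with the same sign in the 4 libraries. A gene needed a value in all 4, whose floors were 5.34 to 16.6 CPM, against 2.91 CPM at 0 min. Weak genes that fell, markers of other cell types included, could therefore drop out, which tilts these counts upward. The median gene of the 0 min library lay 0.29 below its mean over the deeper libraries; with each library centred on its median gene the counts were 437 and 533 and the PHO regulon median 3.17. The reference is 1 library, so no test was made and no error of the reference is known.

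Within the PHO regulon the time of onset was read as the first sample from which the smoothed log2 ratio stayed at or above 0.5 of its 180 to 225 min mean. On the fold scale this lies below 0.5 of the late level for strongly induced genes. The plan asked for members that rose, but none passed the slope test, and genes were taken by their late mean alone. Of 16 genes with a value, 10 reached it at 15 min, the first sample: PHO11, PHO12, PHO81, PHO84, PHO86, PHO89, SPL2, VTC2, VTC3 and VTC4. The other 6 reached it at 30 min: PHO5, PHO8, PPN1, PHM6, PHM8 and GDE1. Without the running mean 14 genes reached it at 15 min, and only PHO5 and GDE1 at 30 min. PHO84 stood at 81.8% of its late log2 ratio at 15 min and PHO81, the inhibitor of the Pho80-Pho85 kinase, at 91.4%. The secreted acid phosphatase gene PHO5 (chromosome II, 429548 to 430951) stood at 36.2%. PHO5 may share reads with PHO3, which was not examined. PHM7 and the glycerophosphoinositol transporter gene GIT1 were not listed at 0 min, and CTF19 in no library. The median onset was 15 min, the sampling step, and 30 min without the library of 15 min.

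**Figure D2:**
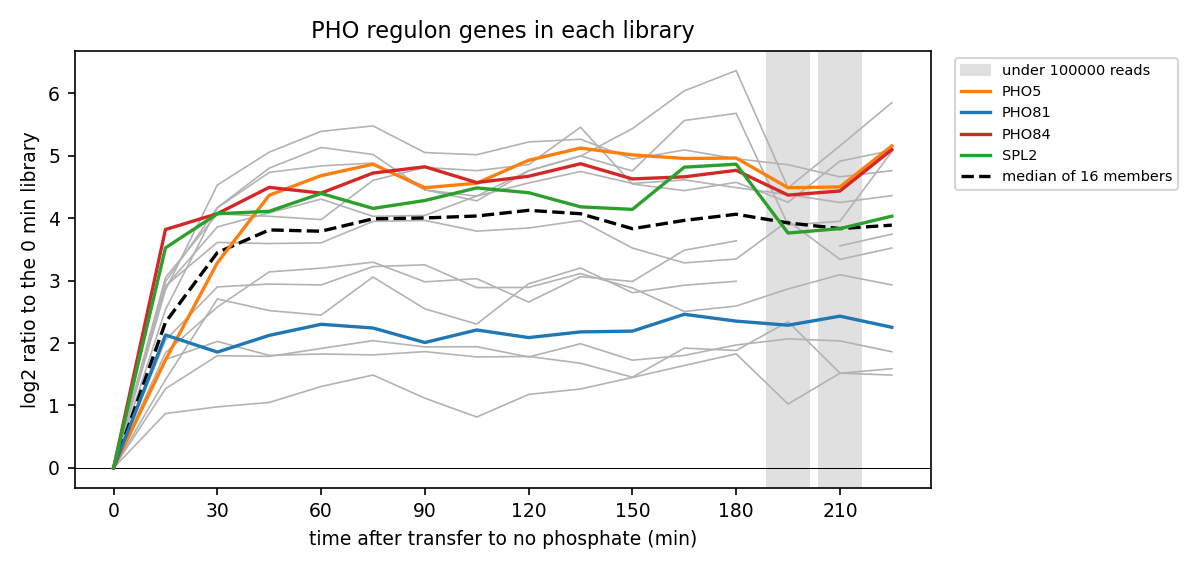
Log2 ratio to the 0 min library (vertical axis) against time in minutes for the 16 PHO regulon genes with a value, with 4 of them coloured, the others in grey and their median dashed; grey bands mark the libraries under 100000 reads. The median is 2.33 at 15 min and lies between 3.45 and 4.12 from 30 min on.

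The last hour, 180 to 225 min, was also compared with 0 min to ask what late starvation looked like. Here a gene needed a value in only 2 of the 4 libraries, and the same sign in those with a value. Most genes have no value at the labels 195 and 210 min. The counts of this window are therefore not comparable with those of the first hour. The PHO regulon remained high, with all 16 genes at least 2-fold up and a median of 3.88 (range 1.49 to 5.46). PHM8 was 44.1-fold higher (5.46 ± 0.82, SD over 4 libraries), PHO11 28.0-fold (4.81 ± 0.12), PHO5 27.4-fold (4.77 ± 0.34), PHO89, a sodium-coupled phosphate transporter, 26.1-fold (4.70 ± 0.37) and PHO84 25.4-fold (4.66 ± 0.34). General stress genes had a median of 3.68 (40 of 40 higher); DDR2, a small stress-induced protein, was 29.7-fold higher (4.89 ± 0.53) and the small heat shock gene HSP26 22.9-fold (4.52 ± 1.29). From 180 and 225 min alone HSP26 was at 5.60 and PHM8 at 6.10 (log2). Genes of trehalose and glycogen (median 2.84, 15 of 17 higher), autophagy and vacuolar hydrolases (2.18, 15 of 17), the TCA cycle (1.78, 13 of 16) and oxidative phosphorylation (1.33, 26 of 35) were higher as well. After centring these 4 medians were 2.27, 1.78, 1.23 and 0.87. Ribosomal protein genes had a median of -1.90 (120 of 136 lower) and ribosome biogenesis genes -1.80 (46 of 57). The 2 shallow libraries stood apart here: the ribosomal protein median was -3.10 at 180 min and -3.51 at 225 min, but -0.44 and -0.52 at the labels 195 and 210 min. In all, 1364 of 4982 genes were higher and 451 lower, 1309 and 555 from 180 and 225 min alone, a choice made after seeing the data. Centring each library on its median gene gave 790 and 724.

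**Figure D3:**
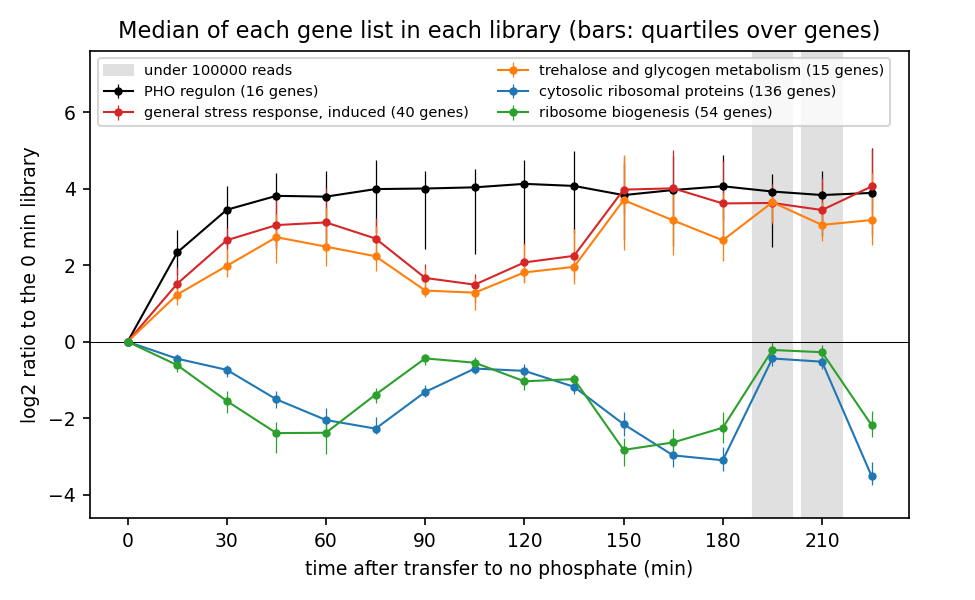
Median log2 ratio to the 0 min library (points; bars span the quartiles over genes) of 5 gene lists against time in minutes; at the labels 195 and 210 min (grey bands, under 100000 reads) only the members listed there enter. The stress list reads 3.12 at 60 min, 1.49 at 105 min and 3.97 at 150 min, and the ribosomal protein list -2.27, -0.70 and -2.97 at 75, 105 and 165 min.

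The slope over the 15 starvation libraries asks which genes went on changing after transfer. HPF1, a cell wall mannoprotein, had the largest fitted rise among called genes with all 15 values, a log2 change of 4.36 ± 0.45 (SE, n = 15 libraries) from 15 to 225 min, or 20.5-fold (adjusted p = 7.88e-05). The stress genes HSP26, SIP18 and DDR2 rose by 3.72 ± 0.74, 3.68 ± 0.84 and 3.25 ± 0.65. YMR175W-A rose by 3.92 ± 0.86; this open reading frame lies just downstream of SIP18 on the same strand, and whether the pair give separate signals was not examined. Smaller rises were those of the chitin deacetylase gene CDA1 (2.06 ± 0.44), the amino acid permease gene AGP1 (1.81 ± 0.37), MCR1, a mitochondrial reductase (1.77 ± 0.41), GRX1, a glutaredoxin (1.68 ± 0.42), YIL014C-A (1.56 ± 0.27), the bud neck gene AIM44 (1.45 ± 0.34) and BUR6, a subunit of a transcription regulator (1.36 ± 0.21). The 3 falling genes with all 15 values were SAM2, S-adenosylmethionine synthetase (-2.05 ± 0.40), MET6, methionine synthase (-1.59 ± 0.30), and CHO2, a methyltransferase of phospholipid synthesis (-1.20 ± 0.28). To have all 15 values a gene had to reach the floors of 244 and 222 CPM at the labels 195 and 210 min. Weaker genes, and genes that had fallen below these floors, could not enter this named set. Over all 5282 genes tested 85 rose and 15 fell at an adjusted p under 0.05 and a fitted change of at least 1 in either direction; the p-values measure only scatter of these 15 libraries around a line in what the labels describe as a single culture.

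Most of these calls rest on few libraries and on treating them as independent. With the lag-1 autocorrelation of 0.36 removed, 3 genes rose and 0 fell, and of the 31 named genes past the test HPF1 alone remained. The fitted changes stayed close to those before: HSP26 was at 4.02 (adjusted p = 0.119), DDR2 at 3.40 (0.113), SAM2 at -2.15 (0.152) and HXT5 at 5.04 (0.0633). Without the libraries labelled 195 and 210 min, a choice made after seeing the data, 164 rose and 174 fell, with 82 and 15 of them shared. HPF1 was then at 5.10, HSP26, SIP18 and DDR2 at 4.67, 3.86 and 3.38, and SAM2 at -2.68. YIL014C-A and AIM44 were smaller than before, at 1.24 and 1.38. Leaving out 1 library at a time, the rising genes were 21 without 15 min, 26 without 30 min, 51 without 90 min, 35 without 150 min, 26 without 165 min, 15 without 180 min and 17 without 225 min. The falling genes were 7, 8, 7, 5 and 1 without 15, 150, 165, 180 and 225 min, and 24 without that labelled 210 min. Centring each library gave 62 rising and 23 falling. Quantile normalization of the 15 libraries gave 76 rising and 169 falling and turned AIM44 and YIL014C-A to -0.34 and -0.26, neither past the test. With the 13 deeper libraries alone, chosen after seeing the data, 0 of 30 named genes reversed under this normalization.

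**Figure D4:**
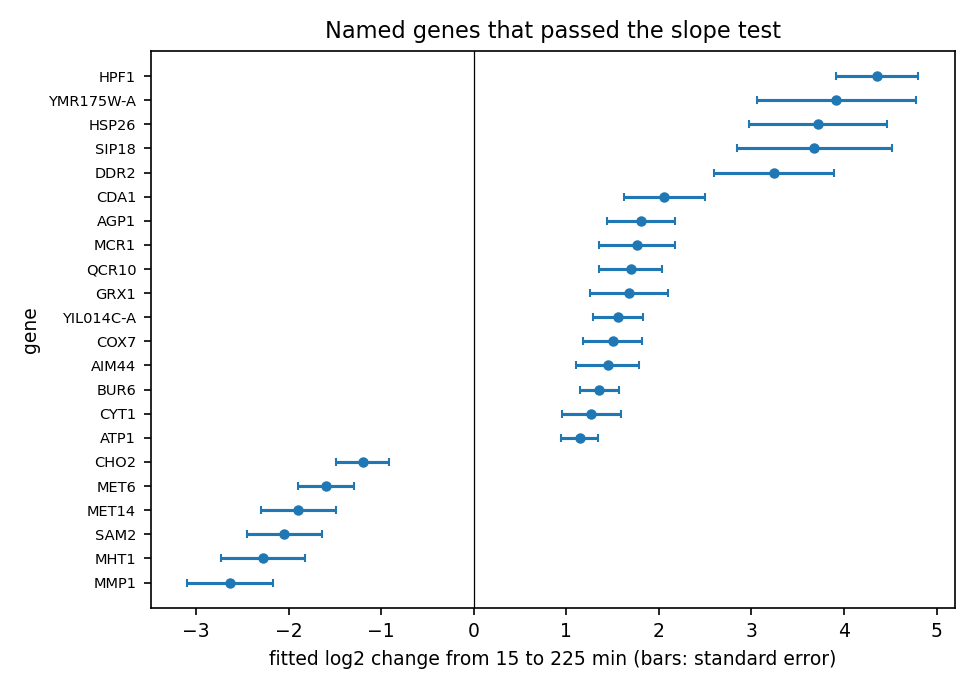
Fitted log2 change from 15 to 225 min (horizontal axis, bars are standard errors), over up to 15 libraries. Drawn are the named genes with the largest slopes among called genes with all 15 values. Named members of the oxidative phosphorylation and sulphur lists are added. The points run from -2.63 for MMP1 to 4.36 for HPF1.

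By gene list, 5 of 42 general stress genes rose (25 adjusted over the list alone), with a median fitted change of 1.71; besides those above, MOH1 rose by 2.79 ± 0.65. The list was higher in slope than other genes by camera (adjusted p = 2.7e-12), but not past the test at adjusted p = 0.514 with an estimated correlation. In oxidative phosphorylation 5 of 35 rose (9 adjusted over the list alone), with a median of 0.92; examples are QCR10 and CYT1 of complex III (1.69 ± 0.34 and 1.27 ± 0.31), COX7 of cytochrome oxidase (1.5 ± 0.31) and ATP1 of the ATP synthase (1.15 ± 0.20). Its adjusted p was 5.31e-12 by camera and adjusted p = 0.25 with an estimated correlation. Sulphur and methionine genes went the other way: 5 of 23 fell (7 adjusted over the list alone), among them MMP1 and MHT1 of S-methylmethionine use (-2.63 ± 0.47 and -2.28 ± 0.45) and MET14 of sulphate assimilation (-1.90 ± 0.40). The median was -0.84, with adjusted p = 2.7e-12 by camera and adjusted p = 0.225 with an estimated correlation. Of the phospholipid list, 2 of 20 fell (2 fell and 1 rose adjusted over the list alone), CHO2 and the CDP-diacylglycerol synthase gene CDS1 (-1.79 ± 0.43). Its median was -0.66, with adjusted p = 0.00147 by camera and adjusted p = 0.225 with an estimated correlation. Without the libraries labelled 195 and 210 min 12 of the 42 stress genes and 8 of the 35 oxidative phosphorylation genes rose, and 8 of the 23 sulphur genes and 6 of the 20 phospholipid genes fell. After centring 2 of the 35 oxidative phosphorylation genes rose, and with the autocorrelation removed 0 genes of these 4 lists passed.

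None of the 17 measured PHO regulon genes passed the slope test (6 rose adjusted over the list alone). Their median fitted change was 0.58, with PHM8 at 1.75 ± 0.48, PHO5 at 1.74 ± 0.55, PHM6 at 1.34 ± 0.47, PHO84 at 0.58 ± 0.26 and VTC3 at 0.03 ± 0.29. The list had adjusted p = 0.0016 by camera, but adjusted p = 0.507 with an estimated correlation, 0.0986 after centring (median 0.28) and 0.231 without the library of 15 min (median 0.38). Without the libraries labelled 195 and 210 min 5 of the 17 rose. No cytosolic ribosomal protein gene passed out of 136 (0 adjusted over the list alone), at a median of -1.13, whereas 108 of 136 fell, at a median of -2.44, without the libraries labelled 195 and 210 min. That list had adjusted p = 5.97e-22 by camera and adjusted p = 0.25 with an estimated correlation. Ribosome biogenesis (0 of 59 called, 0 adjusted over the list alone, median -0.60, or -1.06 without the libraries labelled 195 and 210 min) had adjusted p = 3.9e-06 by camera and adjusted p = 0.567 with an estimated correlation. Of 36 translation factors HEF3, a second gene of an elongation factor, rose by 1.48 ± 0.35 (1 adjusted over the list alone) against a list median of -0.38; camera gave adjusted p = 0.000243, and adjusted p = 0.444 with an estimated correlation. Without the libraries labelled 195 and 210 min 7 of the 36 fell, at a median of -0.78.

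In trehalose and glycogen metabolism NTH2, a trehalase, rose by 1.14 ± 0.26, the only one of 17 (11 adjusted over the list alone), with a list median of 1.28. Camera gave adjusted p = 0.000118, and adjusted p = 0.514 with an estimated correlation. The carboxypeptidase gene PRC1 rose by 1.19 ± 0.29, the only one of 18 autophagy and vacuolar genes (4 adjusted over the list alone, median 0.93), with adjusted p = 0.000835 by camera and adjusted p = 0.514 with an estimated correlation. PCL9, a cyclin of the Pho85 kinase, rose by 1.85 ± 0.43, the only one of 17 M/G1 genes (5 adjusted over the list alone, median 0.79), with adjusted p = 0.000835 by camera and adjusted p = 0.507 with an estimated correlation. No member passed in G2/M genes (15 measured, 2 adjusted over the list alone, median 0.54; camera adjusted p = 0.00147, adjusted p = 0.25 with an estimated correlation). The same was true of the TCA cycle (17, 0 adjusted over the list alone, median 0.68; camera adjusted p = 0.00352, adjusted p = 0.514 with an estimated correlation). Glycolysis and fermentation (17, 3 adjusted over the list alone, median 0.56) gave adjusted p = 0.0105, and adjusted p = 0.514 with an estimated correlation. The proteasome (33, 0 adjusted over the list alone, median -0.11) gave adjusted p = 0.0242, and adjusted p = 0.614 with an estimated correlation. Without the libraries labelled 195 and 210 min PRC1 was no longer called, at 1.11 (adjusted p = 0.0552), nor was it after centring, at 0.89 (0.0915). Without these libraries 4 of 17 trehalose and glycogen, 4 of 17 M/G1, 2 of 17 glycolysis and 1 of 15 G2/M genes rose. The TCA call was lost without 15 min (adjusted p = 0.104) or 225 min (0.0791), that of glycolysis without 15 min (0.205, median 0.35) or after centring (0.377, median 0.26), and that of the proteasome without 30, 45, 60 or 225 min (0.133, 0.252, 0.147 and 0.0649) or with the 0 min library added (0.305). The proteasome median was then -0.04, -0.01, -0.00, -0.07 and 0.10, in this order. It was -0.37 without the libraries labelled 195 and 210 min and -0.40 after centring.

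A spline of 3 degrees of freedom asks which genes moved along a curve, up and back or down and back. ALD4, the mitochondrial aldehyde dehydrogenase gene, changed along a trough (adjusted p = 0.0241): its fitted value at 90 min lay 2.37 (log2) below the lower end, and its log2 ratio to 0 min went from 2.86 at 15 min to 0.16 at 105 min and 3.24 at 225 min. HXT5, a hexose transporter gene listed in 9 of the starvation libraries, had a trough of 1.95 and a rising slope of 5.08 ± 0.73. PHD1, a transcription factor gene, and PLB1, a phospholipase gene, had troughs of 1.00 and 0.85, and YLR154W-E and YDR119W-A, listed in 12 and 9 of the starvation libraries at a mean log2 CPM of 3.83 and 3.56, had troughs of 1.97 and 1.00. Fitted peaks were those of YDR119W-A (0.75 above the higher end, at 165 min), CDC21, the thymidylate synthase gene (0.66, at 90 min), ACO1, aconitase (0.34, at 90 min), and PHO5 (0.19, at 105 min). The fitted peak of PHO5 is not seen in its values. Its log2 ratio to 0 min was 4.56 at 105 min, 5.12 at 135 min and 5.15 at 225 min. At the labels 195 and 210 min it was 4.49 and 4.50. Of 5282 genes 25 passed, 4 with a peak and 14 with a trough inside the range, and 11 had also been called by slope.

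This count depends on the curve allowed. It was 668 at 4 degrees of freedom, with 29 of 42 general stress genes, 14 of 35 oxidative phosphorylation genes, 9 of 17 TCA cycle genes and 11 of 33 proteasome genes among them (hypergeometric adjusted p = 8.22e-16, 0.000652, 0.000767 and 0.0131). At 3 degrees of freedom 0 of 42, 0 of 35, 1 of 17 and 0 of 33 had passed, and no list was enriched (lowest adjusted p = 0.803). At 4 degrees 7 of 20 phospholipid genes (0.0454) and 7 of 17 M/G1 genes (0.0192) also passed, the latter list not enriched at 5 (0.549). The test takes genes as independent, while the estimated correlation within the stress list was 0.81. With the autocorrelation removed 2 genes passed, and 105 passed without the libraries labelled 195 and 210 min. Without single libraries the count was 9 (30 min), 6 (45 min), 11 (75 min), 1 (90 min), 3 (105 min), 6 (120 min), 3 (150 min), 4 (165 min), 1 (180 min) and, rounded, 2.8e+02 (225 min).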

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

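Besides the count alternatives of the report, 13 genes rose and 7 fell with the direction of the spline of 3 degrees of freedom, and 10 and 0 with windows of 180 to 225 against 15 to 60 min. Adding the 0 min library gave 417 and 44, genes listed in all 15 libraries 21 and 4 of 905 (fewer genes tested), and an adjusted p under 0.01 gave 4 and 0. Whitening gave 3 and 0, quantile normalization 169 falling, and centring 23 falling; the cause was not tested. Quantile normalization of the 13 deeper libraries, chosen after seeing the data, gave 176 and 183. Leaving out 1 library gave 15 to 118 rising and 1 to 24 falling genes, and 1 to 2.8e+02 (rounded) along a curve. AIM44 and YIL014C-A reversed under quantile normalization of the 15 libraries, to -0.34 and -0.26; the cause was not tested. Both shallow libraries left out gave 164 rising and 174 falling, also chosen after seeing the data.

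Genes along a curve were 668 with 4 and 1313 with 5 degrees of freedom (the latter added later), 38 after centring, 2 after whitening, 105 without both shallow libraries and 95 of the 4500 genes complete in the deeper ones (both added later). The first hour gave 437 higher genes after centring, and the last hour 790 higher, 724 lower and a PHO regulon median of 3.34, or 4.06 from 180 and 225 min alone. Leaving out 1 library gave PHO regulon medians of 3.76 to 3.95 for the last hour and onsets of 15 to 30 min. Of 15 lists past camera, 0 passed with an estimated correlation and 8 by fry, both on the complete genes: ribosomal proteins (0.0236), G2/M (0.0034), M/G1 (0.0339), oxidative phosphorylation (0.0034), the PHO regulon (0.0274), phospholipid (0.0034), sulphur (0.0034) and translation factors (0.0372). Of 31 named genes past the slope test, 30 remained without both shallow libraries, 23 after centring, 15 after quantile normalization and 5 without 225 min. Under the other settings run (variance models, a minimum of 3 values, weights, no minimum change) both slope counts stayed within 1.5 times the main ones. The floor, taken as 20 reads, leaves 1122 and 1188 genes at the labels 195 and 210 min, so late values of less abundant genes rest on the other libraries.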

Other observations

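Histone and G1/S list medians differed between time points, and no member of either list was called by slope. The histone median was -0.65 at 45 min and 0.60 at 105 min (log2 ratio to 0 min), and HTB2, a gene of histone H2B, went from -1.23 to 0.55 between these times. G1/S genes, which act in DNA replication, reached a median of 0.81 at 75 min. After centring the histone medians were -0.95 and 0.35 and that of G1/S genes 0.40. Over the slope 0 of 8 histone genes were called (1 adjusted over the list alone, median 0.44; camera adjusted p = 0.0557) and 0 of 30 G1/S genes (0 adjusted over the list alone, median 0.13, camera direction down, adjusted p = 0.501). In the spline of 5 degrees of freedom, added after seeing the data, 6 of 8 histone genes, 44 of 58 ribosome biogenesis genes, 18 of 25 Hsf1 chaperone genes and 15 of 17 trehalose and glycogen genes passed (hypergeometric adjusted p = 0.0158, 5.22e-15, 7.05e-06 and 6.71e-07). Of the lists past the test at 4 degrees all but M/G1 passed again. G1/S genes passed in 5 of 30, against 7.46 expected.

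Genes of phosphate signalling and constitutive transport had a first-hour median of 0.58 (0.28 after centring), with the low-affinity transporter gene PHO90 at -2.06 and KCS1, an inositol pyrophosphate kinase gene, at 1.5 at 60 min. Over the slope 0 of 14 were called (1 adjusted over the list alone, median 0.41, adjusted p = 0.134), and 0 of 8 polyphosphate genes (0 adjusted over the list alone, median 0.45, adjusted p = 0.0557), whose first-hour median was 1.45. Hsf1 chaperones had a first-hour median of 1.18, and 1 of 25, HSP26, rose (3 adjusted over the list alone, median 0.29, -0.08 without the libraries labelled 195 and 210 min; adjusted p = 0.275). HXT5 rose among 18 hexose transport and glucose-repressed genes (2 rose and 1 fell adjusted over the list alone, median 0.32, adjusted p = 0.213), and URA10, of pyrimidine synthesis, rose by 2.25 ± 0.55 among 16 zinc regulon genes (1 adjusted over the list alone, median -0.05, adjusted p = 0.275). IMD2, of guanine nucleotide synthesis, fell by -1.31 ± 0.28 among 20 purine genes (1 adjusted over the list alone, median -0.07, adjusted p = 0.309). No gene passed, over all genes or adjusted over the list alone, in amino acid synthesis (42, median -0.11, adjusted p = 0.0557), ergosterol synthesis (24, 0.19, adjusted p = 0.466), the iron regulon (23, 0.10, camera direction down, adjusted p = 0.395), mitochondrial ribosomal proteins (55, 0.16, camera direction down, adjusted p = 0.827) or pheromone response (23, 0.00, camera direction down, adjusted p = 0.358). Nor did any of 9 markers of other cell types (median -0.00, adjusted p = 0.407). The amino acid list passed in 10 of its alternatives, among them without the libraries labelled 195 and 210 min (adjusted p = 0.00802), but not with an estimated correlation (adjusted p = 0.514). Polyphosphate genes and histones passed in 6 alternatives each, with the lowest adjusted p of 0.0101 (0 min library added) and 0.0153 (without 225 min), but not with an estimated correlation (adjusted p = 0.514 and 0.614). Chaperones passed without 30 min (0.0208) or 45 min (0.0275), purine genes after centring (0.0386) and pheromone genes without 15 min (0.0361). With an estimated correlation these gave adjusted p = 0.984, 0.514 and 0.982. After centring the slope medians were -0.29 for amino acid genes, 0.15 for polyphosphate genes, 0.13 for histones, -0.01 for chaperones, -0.37 for purine genes and -0.20 for pheromone genes. Without the libraries labelled 195 and 210 min 2 of 42 amino acid genes fell, 2 of 25 chaperone and 2 of 18 hexose transport genes rose, as did 1 each of the phosphate signalling, purine and pheromone genes.

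Of the tests below, those on VTC1, on the libraries labelled 195 and 210 min and on reads from other libraries were chosen only after the result was seen. Those on depth, scaling and the order of libraries were written down before their own results. The windows used for depth and scaling, however, follow the pattern already seen in the stress list. VTC1, the gene labelled as deleted, was listed in each library and at the labels 195 and 210 min lay 3.67 and 3.77 (log2) above its mean over the deeper libraries. The per-million scale of libraries with few genes is argued against, since the excess was still 3.15 (log2) or more after the shift of the median gene was taken off. Over the 14 deeper libraries VTC1 CPM went with 1/depth (Spearman rho 0.912, permutation p = 2e-05). Pearson r was 0.879 (permutation p = 1e-05, the smallest that 100000 permutations give), and 0.891 without the 2 libraries farthest in 1/depth. The line reached 1566 and 1435 CPM at the labels 195 and 210 min against 1781 and 1911 observed, in the opposite order. It was extrapolated far beyond the fitted range, from at least 1206852 reads to 81968 and 90017. A roughly constant number of reads from other libraries is a candidate explanation, but for part of the VTC1 reads only. The slope was 120 reads, against 214 to 698 VTC1 reads in the deeper libraries. A state of the culture between those of 180 and 225 min is argued against: the centred ribosomal protein median departed from the mean of both by 2.45 (log2) or more, and deeper libraries from their own neighbours by at most 1.01 (SD 0.58). A brief excursion of the culture, other material and a wrong label cannot be told apart, as no deeper library lies between: their slopes on that mean over 309 abundant genes were -0.17 ± 0.02 and -0.140 ± 0.02, but 2 of 20 slopes of deeper libraries on their neighbours were low as well (-0.32 and -0.10), and the constant part of 96.7 VTC1 CPM stays open too.

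General stress genes had a mean list median of 2.95 at 45 to 75 min, 1.74 at 90 to 120 min and 3.91 in the deeper libraries of 150 to 225 min, while ribosome biogenesis genes had -2.05, -0.67 and -2.47 and the PHO regulon stayed at 3.86, 4.05 and 3.93. Library depth is argued against, since the drop between the first pair of windows was 1.22 ± 0.22 (SE, 10 libraries) with log10 depth as a covariate and 1.21 without. Scaling is argued against by a drop of 1.14 after centring, and reads from other libraries of the series by the PHO regulon: the only other libraries with a stress median under 1.74, those of 0 and 15 min, also have low PHO medians (0 and 2.33), yet the PHO median was higher by 0.190 ± 0.13 (log2, SD) at 90 to 120 min. Reads from libraries outside the series cannot be told apart from a change in the culture: VTC1 differed by -0.0225 (log2) at 90 to 120 min from 45 to 75 min, but its level in such libraries is not known. That the culture went through 2 waves of stress gene expression therefore stays an open hypothesis, found and tested on the same libraries, as does other handling between samples.

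For the order of the libraries, 2 of 100 orders, the real one included, called as many genes by slope as the real 100. Along a curve 3 of 100 called as many as the real 25. Both shares lie under the 0.05 set beforehand. Shuffling also removes the autocorrelation between neighbouring libraries (0.36 around the line), so this test cannot tell a trend from drift. The highest other orders called 186 and 156 genes, and the median other order 0.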
